A study of Homo sapiens with 4 samples.

How the data were processed

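RNA from MCF-7 cells was sequenced in 4 libraries, 1 each of untreated control, E2, PPD and PPT, as the labels name them. The 3 treated libraries were exposed for 48 h, and the labels give no time for the control and no dose for any library. Total RNA was extracted and libraries were prepared by a standard Illumina procedure, per the labels' protocols. Base calls were converted with bcl2fastq 2.17.1.14, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the genome build were not given in the sources used here.

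The authors deposited raw counts and FPKM values (fragments per kilobase of exon, scaled to the library total) for 60612 Ensembl genes, with 1 column of each per library, per the file headers. The deposited FPKM values equal the count divided by the exonic gene size and the library's total count in 242448 of 242448 values, within the rounding to 2 decimals. The other deposited measure, the exonic gene size, was used only as a length. Gene starts and ends equalled those of GENCODE release 29 on GRCh38 for both coordinates in 44970 of the 58394 genes with an identifier found there (77.0%), and coordinates are printed as deposited, counted from 1. Because counts were taken over exons with no strand setting named, overlapping and antisense genes and near-identical copies can share counts.

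Depth was 16101098 counts in control, 18727209 in E2, 19179611 in PPD and 16031231 in PPT. A count of 0 allows up to 3 counts, or 0.186, 0.160, 0.156 and 0.187 CPM in the 4 libraries. Of the 12504 genes with a mean of at least 1 FPKM, 1118 had a mean count under 50, and these set the limit of the 2-fold counts.

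The comparisons, the size rule, the gene lists and the alternatives were fixed before the data were examined. They were E2, PPD and PPT each against control, and PPT against PPD. PPD and PPT against E2 were added after the data were seen, as was a minimum mean count of 50. With 1 library per group no statistical test was possible, and differences were described by size. A gene counted as different when log2(FPKM + 1) differed by at least 1 between the libraries, among genes with a mean of at least 1 FPKM. Exact intervals (Clopper-Pearson on the split of 2 counts for folds, exact Poisson for FPKM, Clopper-Pearson for shares) were taken at 95%. They cover counting error at most. They take reads as independent molecules, which sequencing reads are not, so they can be too narrow even for counting error. Counting noise was simulated 100 times with Poisson counts at the pooled rate of each gene and the real library totals.

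Genes were named by a rule fixed in advance: the 10 highest and 10 lowest differences per comparison among genes with a symbol and a mean of at least 1 FPKM, up to 4 members of each list with the largest difference, and GREB1, TFF1, PGR, PDZK1 and ESR1 always. Because the ends of these rankings were short RNA genes with few counts, only examples of them are printed. The same ranking among genes with a mean count of at least 50 was added after the values were seen, and RAMP3, SFXN2, SYTL5, PRSS23, LINC01016, CLEC3A, GRHL3, NRAD1, SERHL2, KRT81, KRT86, S100A9, NUS1P1, DHFRP1, DNAJB6P1, FAM3C2, EIF3CL, NPIPA9 and MORN4 come from it. CDKN2B, IGFBP3, ITGB6 and some list members outside the largest 4 (MYB, STC2, RET, KRT8, KRT18, BUB1, CDC20 among them) were also chosen after their values were seen. The intervals make no allowance for the choice of a gene by its value.

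The 22 gene lists covered estrogen-induced and estrogen-repressed genes, proliferation, cholesterol synthesis, liver X receptor and lipogenic genes, endoplasmic reticulum stress and ATF4 targets, NRF2 targets, aryl hydrocarbon receptor and xenobiotic genes, glucocorticoid and androgen response, p53 targets, interferon response, hypoxia and glycolysis, immediate early and MAPK genes, apoptosis regulators, nuclear receptors and cofactors, luminal, basal and mesenchymal, and blood and endothelial markers, mitochondrially encoded genes, ribosomal proteins, replication histones and metallothioneins. They came from general knowledge and were not chosen on these libraries, and 395 of their 396 entries matched the table. Some genes stand in more than 1 list. For each list the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Gene Ontology terms of the deposited table were treated in the same way with 300 random lists, for terms with 15 to 500 genes.

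Correlations, covariances and overlaps of comparisons that shared the control library were set beside values simulated without effects, and beside contrasts with no library in common. The calculations were tested on simulated data. These data held 12504 genes, with 100 genes changed by each fold. The changed genes were drawn only from those with a mean count of at least 50 and a mean of at least 5 FPKM. Among them the size rule recovered 91% of 2.5-fold changes in E2 against control and 92% in PPD against control. It recovered 94% in PPT against control, 93% in PPT against PPD, and 100% of 4-fold changes in each of these comparisons. The intervals held the true fold in 89% to 98% of changed genes. Recovery was not tested for genes with fewer counts, which made up most of the genes counted as different. The values were recomputed with pseudocounts of 0.1 and 5, no expression filter, a mean of at least 5 FPKM, median-ratio scaling and scaling to TPM. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.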

Results

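Gene expression was measured by RNA sequencing in MCF-7 cells, an established human breast cancer line that expresses estrogen receptor alpha and divides in response to estrogen. The cells were kept without phenol red, itself a weak estrogen, and in serum stripped of steroids with charcoal and dextran. The data comprised 4 libraries, 1 per condition: untreated control cells, and cells exposed to E2 (estradiol, the main natural estrogen), PPD or PPT for 48 h. PPD (protopanaxadiol) and PPT (protopanaxatriol) are the triterpene cores left when the sugars of ginseng saponins are removed, and PPT carries an additional hydroxyl group. The doses of the sequenced libraries were not given in the labels, which name several concentrations, so the comparisons between compounds were matched in time and of unknown match in dose. The series title places the question in the estrogen receptor alpha activity of ginsenoside metabolites.

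The libraries held 16101098 counts for control, 18727209 for E2, 19179611 for PPD and 16031231 for PPT, and between 23038 and 23614 genes had at least 1 count. Of the 60612 genes listed, 12504 had a mean of at least 1 FPKM over the 4 libraries. Genes of the mitochondrial chromosome took 5.86% of counts in control (95% exact interval 5.85 to 5.88), 6.09% in E2 (6.08 to 6.10), 6.18% in PPD (6.17 to 6.19) and 6.58% in PPT (6.57 to 6.59). With 1 library per condition no difference had a replicate check and no p-value was computed, so each statement compares these libraries and not the conditions. All intervals are 95% intervals of the counts and cover counting error at most. Folds are ratios of counts scaled to the library totals, and log2 differences are on the log2(FPKM + 1) scale, which understates differences of low genes.

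Genes that estrogen is known to induce in MCF-7 cells were lower in the library labelled E2 than in the library labelled control. GREB1, an estrogen receptor cofactor and growth regulator, stood at 21.3 FPKM in control (20.6 to 21.9) and 7.68 FPKM in E2 (7.33 to 8.05), a 2.77-fold higher level in control (2.62 to 2.93). PGR, the progesterone receptor, was 2.64-fold higher in control (2.29 to 3.05), and TFF1, a secreted trefoil peptide, 1.72-fold (1.68 to 1.75). The chemokine gene CXCL12 was 2.88-fold higher in control (2.25 to 3.72), and the fatty acid elongase gene ELOVL2 2.96-fold (2.16 to 4.09). PDZK1, a scaffold protein gene under the expression filter, had 31 counts in control and 12 in E2, a 3.0-fold difference (1.5 to 6.4).

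Of the 40 genes of the estrogen-induced list 35 were measured, of which 33 were lower and 2 higher in the library labelled E2. Their median log2 difference was −0.38, below every one of 10000 random lists matched on expression (central 95%, −0.04 to 0.05). Further members with large differences were KRT13 (−0.86), PKIB (−0.79), EGR3 (−0.76) and SERPINA1 (−0.76). The estrogen-repressed list was higher in the library labelled E2, with 15 of 19 measured members higher and a median of 0.22, above every random list. Its members BCAS1, IL1R1 and PSCA were 1.79-fold (1.72 to 1.87), 1.56-fold (1.30 to 1.88) and 1.54-fold (1.23 to 1.92) higher in E2, and LCN2, a secreted iron-siderophore carrier, 1.90-fold (1.15 to 3.22) on 53 counts against 24. ESR1, which encodes estrogen receptor alpha, was 1.07-fold higher in E2 (1.04 to 1.10). These directions were opposite to those known for estradiol, so the 2 libraries are named by their labels wherever a direction is drawn from them.

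Outside the lists, RAMP3, a receptor activity-modifying protein gene, was 2.23-fold higher in control (1.88 to 2.65), and SFXN2, a mitochondrial carrier gene, 2.04-fold (1.90 to 2.19). SYTL5, a vesicle trafficking gene, was 2.0-fold higher in control (1.8 to 2.2). The lectin gene CLEC3A was 1.96-fold higher in E2 (1.8 to 2.2), the epithelial transcription factor gene GRHL3 2.09-fold (1.81 to 2.42) and the long noncoding RNA NRAD1 2.15-fold (1.85 to 2.5). Genes of the proliferation list were slightly lower in the library labelled E2, 25 of 34 in number, with a median of −0.06 (percentile 0.07 among random lists). CDC20 and BUB1, regulators of mitosis, were 1.12-fold (1.05 to 1.19) and 1.11-fold (1.03 to 1.19) higher in control.

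By the size rule 40 genes were higher and 41 lower in the library labelled E2 than in control, and 77 of these 81 had a mean count under 50. Simulated libraries with counting noise and no differing gene gave 32 to 57 such genes in 100 simulations. The 10 highest and 10 lowest genes were mostly short RNA genes with at most 16 counts in any library, such as MIR8075, with 7 counts in E2 and 0 in control, and MIR6832, with 0 in E2 and 5 in control. Among genes with a mean count of at least 50, a limit chosen after the data were seen, GREB1, RAMP3 and the pseudogene NUS1P1 were at least 2-fold lower on the log2(FPKM + 1) scale and the pseudogene DHFRP1 at least 2-fold higher. NUS1P1 and DHFRP1 share sequence with their parent genes, and their values are uncertain.

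**Figure D1:**
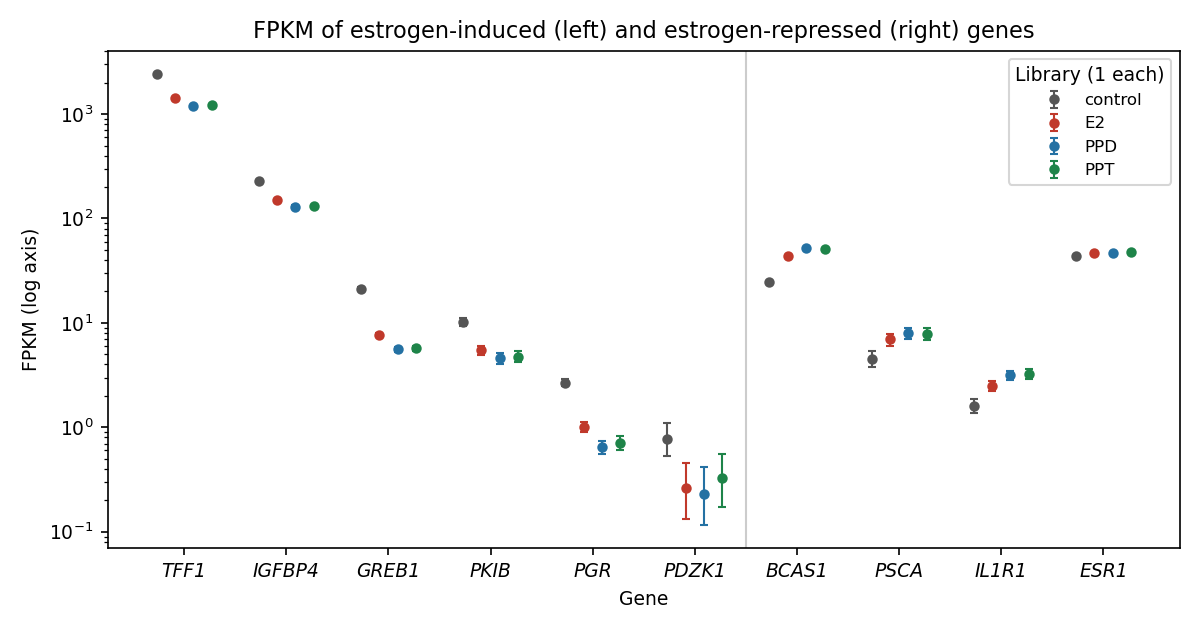
FPKM on a log axis of named estrogen-induced genes (left of the line), and of estrogen-repressed genes with ESR1 (right), in each of the 4 libraries; points are single libraries and bars are 95% exact Poisson intervals of the counts. The induced genes were highest in the library labelled control, with GREB1 at 21.3 FPKM there and 5.57 FPKM in PPD, while BCAS1 was lowest in control at 24.4 FPKM.

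The PPD library differed from control in the same direction in most estrogen-related genes, and in many by more than the library labelled E2. GREB1 was at 5.57 FPKM (5.27 to 5.87), 3.82-fold lower than in control (3.59 to 4.07). PGR was 4.13-fold (3.50 to 4.90), CXCL12 4.09-fold (3.09 to 5.47), TFF1 2.04-fold (1.99 to 2.08) and PDZK1, on 11 counts, 3.36-fold (1.64 to 7.40) higher in control. Of the 35 measured estrogen-induced genes 34 were lower in PPD, with a median of −0.52, below every random list (central 95%, −0.05 to 0.05). PKIB, an inhibitor of protein kinase A, was 2.22-fold higher in control (1.93 to 2.56), STC2, a secreted glycoprotein gene, 1.81-fold (1.74 to 1.89) and the proto-oncogene MYB 1.86-fold (1.68 to 2.05). Some genes differed less in PPD than in E2, among them ELOVL2, with a log2 difference of −0.67 in PPD and −0.89 in E2, and EGR3, with −0.70 and −0.76.

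The estrogen-repressed list had a median of 0.29 in PPD against control, above every random list, with 15 of 19 members higher. BCAS1 was 2.15-fold (2.07 to 2.25), IL1R1, the interleukin receptor gene, 1.97-fold (1.65 to 2.35), PSCA 1.76-fold (1.42 to 2.19) and TP53INP1 1.56-fold (1.42 to 1.71) higher in PPD, while LCN2, at 1.26-fold (0.731 to 2.21), differed less than in E2. ESR1 was 1.07-fold higher in PPD (1.04 to 1.10). Outside the lists, GRHL3 was 2.52-fold (2.20 to 2.91), CLEC3A 2.29-fold (2.08 to 2.53) and NRAD1 2.55-fold (2.20 to 2.96) higher in PPD. SERHL2, on 101 counts against 20, was 4.24-fold higher (2.61 to 7.23). Its level was low, at 0.44 FPKM in control, 0.97 in E2, 1.87 in PPD and 1.15 in PPT. The hair keratin genes KRT81 and KRT86 were 2.04-fold (1.82 to 2.28) and 2.61-fold (1.96 to 3.52) higher, but their sequences are nearly identical and how the counts were split between them is uncertain. RAMP3, SFXN2, SYTL5 and the serine protease gene PRSS23 were 2.68-fold (2.23 to 3.22), 2.54-fold (2.35 to 2.75), 2.43-fold (2.22 to 2.67) and 2.28-fold (2.12 to 2.47) higher in control. The proliferation list had 27 of 34 members lower in PPD and a median of −0.09, below every random list.

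By the size rule 53 genes were higher and 54 lower in PPD than in control, 89 of the 107 with a mean count under 50, and simulations without differing genes gave 30 to 60. The 20 genes at the ends of that ranking were again mostly short RNA genes and pseudogenes, such as MIR5587, with 13 counts in control and 2 in PPD, and AC007229.1, with 0 in control and 26 in PPD. With a mean count of at least 50, 6 genes were higher and 12 lower, where the simulations gave 0. Against the library labelled E2 instead, 0 were higher and 1, the pseudogene DNAJB6P1, was lower, within the 0 to 1 of the simulations. The highest gene above control was a pseudogene of 96 bases, on 69 counts against 23. KRT86 among the higher genes, and the pseudogenes DNAJB6P1 and NUS1P1 among the lower, were also counted, and their values are uncertain.

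The PPT library showed the same pattern against control. GREB1 was at 5.73 FPKM (5.40 to 6.07), 3.71-fold lower than in control (3.48 to 3.97). PGR was 3.76-fold (3.17 to 4.49), CXCL12 2.92-fold (2.24 to 3.84), TFF1 1.99-fold (1.94 to 2.04) and PDZK1, on 13 counts, 2.37-fold (1.21 to 4.94) higher in control. The estrogen-induced list had 34 of 35 members lower in PPT and a median of −0.47, below every random list (central 95%, −0.05 to 0.04). EGR3, a zinc finger transcription factor gene, was 2.06-fold (1.80 to 2.36) and RET, a receptor tyrosine kinase gene, 1.75-fold (1.64 to 1.87) higher in control. CELSR2, an abundant cadherin receptor gene, was 1.83-fold higher in control (1.79 to 1.87). The estrogen-repressed list had 16 of 19 members higher and a median of 0.26, above every random list, and ESR1 was 1.09-fold higher in PPT (1.06 to 1.12).

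BCAS1, IL1R1 and PSCA were 2.07-fold (1.99 to 2.16), 2.03-fold (1.70 to 2.44) and 1.75-fold (1.40 to 2.19) higher in PPT than in control. CLEC3A was 2.26-fold (2.05 to 2.5), GRHL3 2.41-fold (2.09 to 2.79) and S100A9, a calcium-binding protein gene, 2.47-fold (1.54 to 4.06) higher in PPT, the last on 64 counts against 26. RAMP3 was 2.93-fold (2.40 to 3.59), SYTL5 2.45-fold (2.22 to 2.71) and the long noncoding RNA LINC01016 2.90-fold (2.25 to 3.77) higher in control. The proliferation list had 29 of 34 members lower and a median of −0.09, below every random list, although CCNE1, which encodes cyclin E, was 1.41-fold higher in PPT (1.18 to 1.69). All 13 protein-coding genes of the mitochondrial chromosome were higher in PPT, with a median of 0.18, above every random list, beside the higher mitochondrial share of that library.

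By the size rule 62 genes were higher and 50 lower in PPT than in control, 98 of the 112 with a mean count under 50, and simulations without differing genes gave 32 to 64. The ends of the ranking were MIR6746, with 6 counts in PPT and 0 in control, and MIR4746, with 0 in PPT and 8 in control. With a mean count of at least 50, 8 genes were higher and 6 lower, where the simulations gave 0. Against the library labelled E2 these numbers were 2 and 0, where the simulations gave at most 1. Of the 2, 1 was NPIPA9, with uncertain counts, and the other had 101 counts in PPT against 50 in E2. The counts for both compounds thus rest on which library is taken as the control. The 8 genes higher than control included a pseudogene of 96 bases, the highest, on 61 counts against 23. NPIPA9 and the pseudogene DHFRP1 were also among the 8, and their counts are uncertain.

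PPD and PPT were compared directly to find where compounds that differ by a hydroxyl group differed in the response. In the estrogen genes they lay close together, with PPT over PPD at 1.03 for GREB1 (0.95 to 1.12), 1.10 for PGR (0.884 to 1.36), 1.02 for TFF1 (0.995 to 1.05) and 1.02 for ESR1 (0.993 to 1.05). The interval for CXCL12, 1.40 (0.991 to 1.98), allowed a difference of nearly 2-fold. The estrogen-induced list had 23 of 35 members higher in PPT and a median of 0.02, at percentile 96.3 of random lists, and the estrogen-repressed list a median of −0.01 (percentile 40.9). Beyond their counting intervals, 5 estrogen-induced members were higher and 2 lower in PPT, and 0 estrogen-repressed members were higher and 3 lower.

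Small differences between the 2 compounds lay in other groups. The mitochondrially encoded genes were higher in PPT in 12 of 13 cases, with a median of 0.09, above every random list. The genes of cholesterol synthesis had 16 of 22 members lower in PPT and a median of −0.06 (percentile 0.13), and the list of liver X receptor targets and lipogenic enzymes 15 of 16 lower with a median of −0.05 (percentile 1.72). CDKN2B, an inhibitor of cyclin-dependent kinases, was 1.31-fold higher in PPD (1.11 to 1.55), and MORN4 1.85-fold (1.42 to 2.42). Both genes were picked after their values were seen, and the intervals do not allow for that choice. DNAJB6P1 and FAM3C2, both pseudogenes, and EIF3CL and NPIPA9, members of families of near-identical copies, were 2.14-fold (1.66 to 2.78), 2.13-fold (1.56 to 2.94), 2.09-fold (1.78 to 2.47) and 3.11-fold (2.20 to 4.45) higher in PPT, all with uncertain counts.

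By the size rule 42 genes were higher and 36 lower in PPT than in PPD, and all 78 had a mean count under 50, the highest being MIR6746, with 6 counts in PPT and 0 in PPD. Simulations without differing genes gave 31 to 64. Among genes with a mean count of at least 50, 0 reached the size rule in either direction, and 11 were higher and 8 lower by at least 1.5-fold. No simulation was run at 1.5-fold, so how many of these counting noise alone would give is not known. In the ranking with this minimum count, the 10 highest genes included 6 pseudogenes and the 10 lowest 4.

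**Figure D2:**
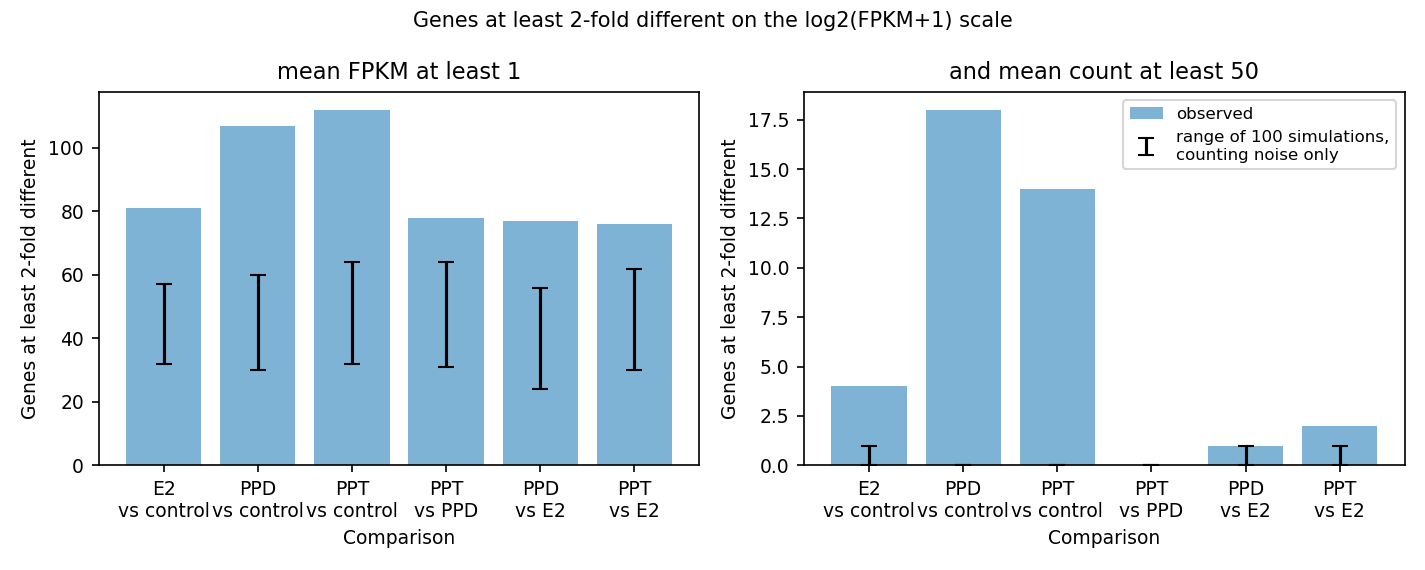
Number of genes at least 2-fold different on the log2(FPKM + 1) scale in each of 6 comparisons (bars), among genes with a mean of at least 1 FPKM (left) and also a mean count of at least 50 (right); black ranges span 100 simulations with counting noise only. On the right PPD against control reached 18 genes and PPT against control 14, while PPD against E2 had 1, PPT against E2 had 2 and PPT against PPD had 0.

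Similarity to the library labelled E2 was measured across genes, which are not independent replicates, from the differences against the shared control. Over 12504 genes Pearson's r between E2 and PPD was 0.649 (Spearman's rho 0.654), between E2 and PPT 0.634 (0.612) and between PPD and PPT 0.670 (0.662). Libraries simulated without effects, which share only the control, gave 0.543, 0.513 and 0.529. The covariances were 0.0325, 0.0328 and 0.0378 against simulated 0.0126, 0.0125 and 0.0127. Without the genes of both estrogen lists the correlations were 0.640, 0.625 and 0.660. The control was a single library and could not be split, so part of the excess may come from the shared control. Contrasts with no library in common gave an r of 0.00613 for E2 minus control with PPT minus PPD, 0.115 for PPD minus control with PPT minus E2 and 0.110 for PPT minus control with PPD minus E2. With a mean count of at least 50 these were −0.0497, 0.149 and 0.204, so the first r changed sign and the last nearly doubled. Spearman's rho moved less, from −0.0497, 0.119 and 0.169 over 12504 genes to −0.0636, 0.134 and 0.198, with no change of sign. Each of these pairs holds a contrast between treated libraries, in which an effect equal in E2, PPD and PPT cancels. The pairs therefore cannot show or refute an effect common to all treated libraries.

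Genes at least 2-fold higher than control were shared by E2 and PPD in 20 cases, by E2 and PPT in 18 and by PPD and PPT in 26, where libraries simulated without effects, with the same shared control, gave medians of 11, 10 and 10 and at most 18, 19 and 19. The overlap of E2 and PPT was thus within that range. Shared genes at least 2-fold lower numbered 14, 13 and 19, against simulated medians of 6, 5 and 6 and at most 12, 10 and 13. Most of these genes had few counts: with a mean count of at least 50, the shared genes numbered 0, 1 and 4 higher and 3, 2 and 5 lower, where the simulations gave 0.

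Set against the library labelled E2 instead of control, PPD and PPT were lower still in estrogen-induced genes, and some other groups differed by about as much. Of the 35 measured, 30 were lower in PPD, with a median of −0.11, and 32 in PPT, with a median of −0.09 (percentiles 0 and 0.01). GREB1 in PPD was 0.724 of its level in E2 (0.674 to 0.778) and in PPT 0.746 (0.692 to 0.804). PGR stood at 0.639 (0.527 to 0.773) and 0.702 (0.576 to 0.853) of that level, and TFF1 at 0.843 (0.822 to 0.864) and 0.862 (0.839 to 0.885). BCAS1 was 1.20-fold higher in PPD than in E2 (1.16 to 1.24) and 1.16-fold higher in PPT (1.12 to 1.20). The ribosomal proteins were lower than in E2 in 23 of 24 cases in PPD, with a median of −0.05, and in 24 of 24 in PPT, with −0.07, and the mitochondrially encoded genes higher in 13 of 13 in PPT, with 0.11. Medians for PPD against E2 also lay outside the central 95% of random lists for cholesterol synthesis (0.05), immediate early and MAPK genes (0.08), replication histones (−0.07) and, narrowly, mitochondrially encoded genes (0.01). The estrogen-repressed list had 0.08 in PPD and 0.05 in PPT. Over the 4 libraries 33 of the 35 estrogen-induced genes were highest in control, and 27 followed the order of control, then E2, then both PPD and PPT. Of the 19 estrogen-repressed genes 15 were lowest in control and 12 followed the reverse order. Independent genes would give 8.75 induced genes highest in control. The genes of a list share the same 4 libraries and are not independent, so these numbers restate the list medians.

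**Figure D3:**
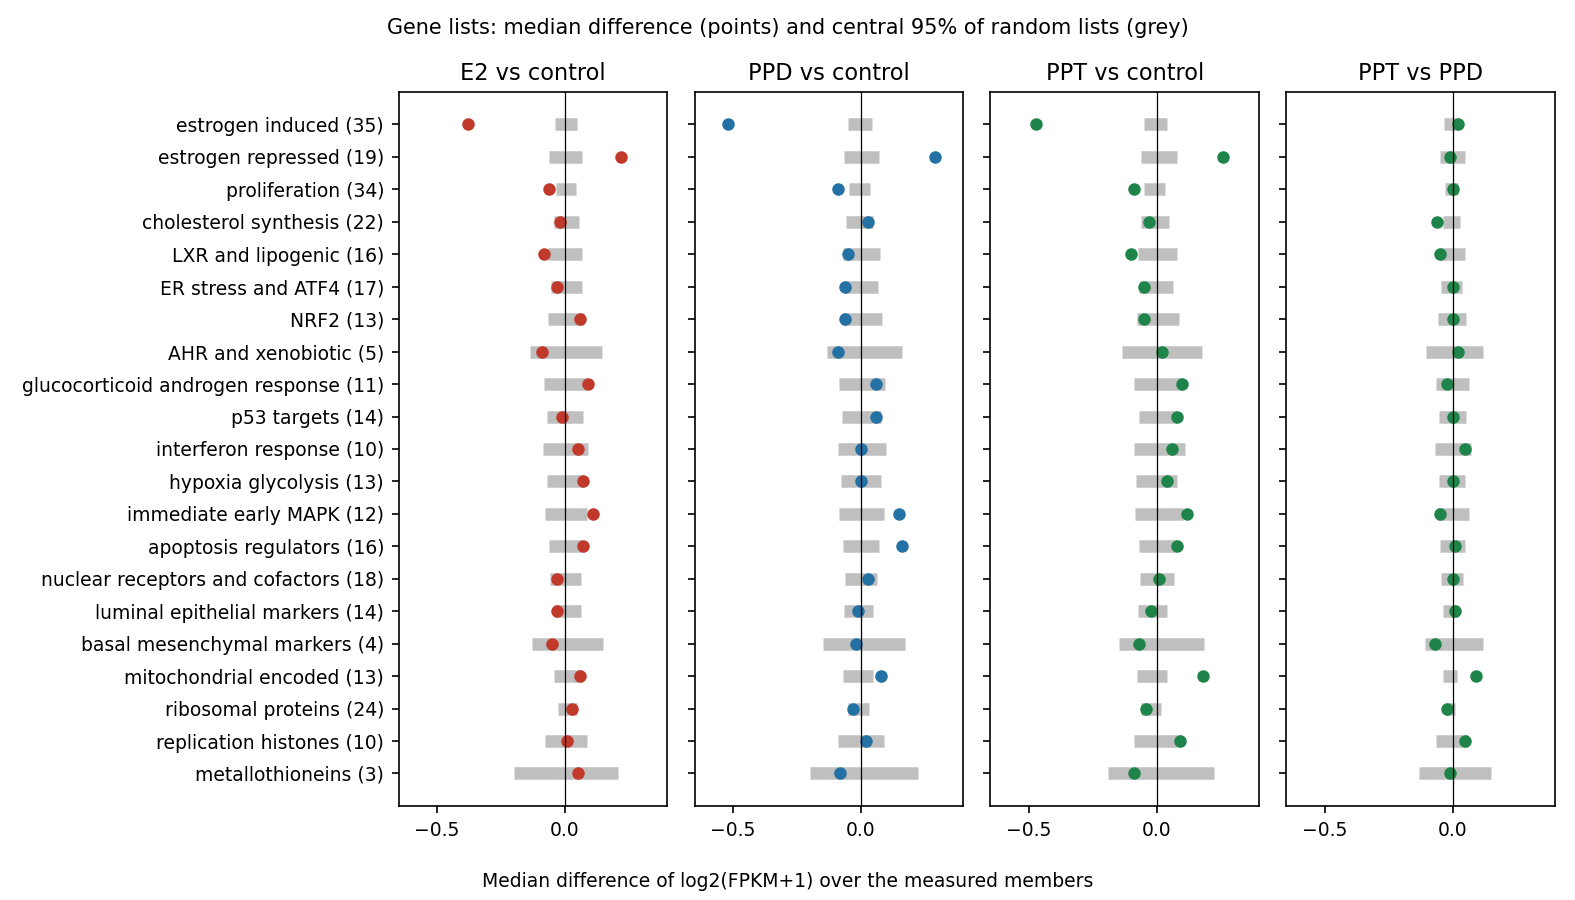
Median difference of log2(FPKM + 1) over the measured members of each gene list (points) in 4 comparisons, with the number of measured members in brackets and the central 95% of 10000 random lists matched on expression (grey). The estrogen-induced list lay at −0.38, −0.52 and −0.47 against control and at 0.02 between PPT and PPD.

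Other gene groups differed less from control. The list of immediate early and MAPK target genes had medians of 0.11 in E2, 0.15 in PPD and 0.12 in PPT, each above the central 95% of random lists, with members on both sides: EGR1 was 1.46-fold higher in PPD (1.18 to 1.80) and DUSP5 1.43-fold lower (1.05 to 1.95). Bootstrap intervals over the members included 0 in each comparison (−0.15 to 0.16, −0.006 to 0.34 and −0.21 to 0.25). The apoptosis regulators had medians of 0.07, 0.16 and 0.08, above that range in PPD and PPT and at its upper end in E2. CASP9, an initiator caspase, was 1.56-fold higher in PPT (1.26 to 1.95), and PMAIP1, which encodes the pro-apoptotic protein NOXA, 1.43-fold lower (1.08 to 1.89). Glucocorticoid and androgen response genes had medians of 0.09, 0.06 and 0.10, above the range in E2 and PPT. Their bootstrap intervals included 0 in E2 (−0.11 to 0.16) and in PPT (−0.23 to 0.24), where 6 members were higher and 5 lower. Liver X receptor and lipogenic genes had medians of −0.08, −0.05 and −0.10, below the range of random lists in E2 and PPT. The bootstrap interval excluded 0 in E2 (−0.19 to −0.03) and included it in PPT (−0.22 to 0.007). The mitochondrially encoded genes had medians of 0.06 in E2, within the range of random lists, and 0.08 in PPD, above that range. With this many lists some fall outside the range by chance.

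The remaining lists lay within the central 95% of random lists in E2, PPD and PPT against control. The medians, in that order, were −0.02, 0.03 and −0.03 for cholesterol synthesis, −0.03, −0.06 and −0.05 for endoplasmic reticulum stress and ATF4 targets, and 0.06, −0.06 and −0.05 for NRF2 targets. Aryl hydrocarbon receptor and xenobiotic genes had −0.09, −0.09 and 0.02 over 5 measured members, among them TIPARP, 1.46-fold lower in PPT (1.29 to 1.66). The p53 targets had −0.01, 0.06 and 0.08, interferon response genes 0.05, 0.00 and 0.06, and hypoxia and glycolysis genes 0.07, 0.00 and 0.04. Nuclear receptors and cofactors had −0.03, 0.03 and 0.01, ribosomal proteins 0.03, −0.03 and −0.04, replication histones 0.01, 0.02 and 0.09, and the 3 measured metallothioneins 0.05, −0.08 and −0.09.

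Markers of the luminal epithelium, the cell type of MCF-7, had medians of −0.03, −0.01 and −0.02, and KRT8 and KRT18, the simple epithelial keratins, were 1.05-fold (1.04 to 1.06) and 1.07-fold (1.06 to 1.08) higher in E2 than in control. Basal and mesenchymal markers had −0.05, −0.02 and −0.07 over 4 measured genes, the most abundant being CD44 at up to 20.8 FPKM. Of the 10 blood and endothelial markers 0 passed the expression filter, and the highest value was 0.81 FPKM for HBA1.

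In the coordinates of the deposited table, GREB1 (ENSG00000196208) lies on chromosome 2 from 11482341 to 11642788 and TFF1 (ENSG00000160182) on chromosome 21 from 42362282 to 42366535. PGR (ENSG00000082175) lies on chromosome 11 from 101029624 to 101129813, PDZK1 (ENSG00000174827) on chromosome 1 from 145670852 to 145708148, and ESR1 (ENSG00000091831) on chromosome 6 from 151656691 to 152129619. BCAS1 (ENSG00000064787) lies on chromosome 20 from 53936777 to 54070594, GRHL3 (ENSG00000158055) on chromosome 1 from 24319357 to 24364482 and CLEC3A (ENSG00000166509) on chromosome 16 from 78022515 to 78066761. All values are sums over the exons of each gene, and no build is named in the sources used here.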

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

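The minimum mean count of 50 and the use of the library labelled E2 as the reference were chosen after seeing the data. The alternatives were run on the 2-fold counts, the estrogen-induced medians, the correlations with E2 and the named genes; no other list was rerun. None of these medians or correlations, and no named gene whose counting interval excluded equality, changed direction: of the comparison values 28 stayed within their yardstick and 39 moved beyond it, and of 1332 values for 61 named genes 118 moved and 0 reversed. For single genes the absence of reversals was nearly fixed in advance. A pseudocount cannot change the sign of a difference and a filter leaves a gene's value unchanged, so only the scalings could reverse it. The yardstick was a factor of 1.5 for counts of genes and, for other values, a bootstrap or counting interval, since there were no replicates. No paired analysis was possible because each group held 1 library. Median-ratio scaling was nearly void, with factors within 0.1% of 1. The counts of 2-fold genes moved under every other setting fixed in advance. For E2, PPD and PPT against control and PPT against PPD, in that order, they were 213, 257, 269 and 180 with a pseudocount of 0.1, and 4, 5, 7 and 1 with a pseudocount of 5. They were 206, 225, 248 and 184 with no filter, and 9, 16, 21 and 2 at a mean of at least 5 FPKM. TPM scaling gave 607, 596, 667 and 533, because FPKM values sum to less than TPM values do, and scaling them up lowers the effective pseudocount and filter. A mean count of at least 50 gave 4, 18, 14 and 0, since that filter by construction removes genes with few counts. The PPD median of the estrogen-induced list was −0.39 with a pseudocount of 5. With the library labelled E2 as the reference the medians were −0.11 for PPD and −0.09 for PPT. The correlation with E2 was 0.613 for PPD and 0.600 for PPT at a pseudocount of 0.1, 0.713 and 0.686 at 5, 0.596 and 0.573 with no filter, 0.771 and 0.749 at 5 FPKM, 0.594 and 0.571 in TPM, and 0.762 and 0.727 at 50 counts. For the medians and correlations the cause was not tested.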

Other observations

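All tests weighed below were chosen after the results they bear on had been seen. The test of exchanged labels first used the estrogen-repressed list, which restated the pattern, and was replaced by the proliferation list with its values already known. The test of a difference of the control library first used only contrasts without control. Since the control cannot enter these, it was replaced. The test of scaling first used other scalings, which move all genes of a library alike, and was replaced by matched random lists.

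Gene Ontology terms were examined beyond the lists, and those named here were picked from 1171 overlapping terms after their values were seen. More terms than the 7.27 per tail expected of independent ones lay at least 2.5 standard deviations from their random lists: 19 higher and 38 lower in E2 than in control, 39 and 34 in PPD, and 12 and 30 in PPT. Between treated libraries there were 22 and 19 in PPD against E2, 4 and 18 in PPT against E2, and 8 and 17 in PPT against PPD. An excess was thus not particular to the comparisons with control. Against control, the lysosomal membrane term, with 108 genes, had medians of 0.05, 0.06 and 0.05 in E2, PPD and PPT, above every one of 300 random lists, and the Golgi membrane term, with 312, had 0.03, 0.04 and 0.02. Cell adhesion genes had 0.05, 0.05 and 0.03, and in PPT neither this term nor the Golgi membrane term reached 2.5 standard deviations. The keratin filament term, with 15 genes that include the near-identical KRT81 and KRT86, had 0.10, 0.21 and 0.14. RNA binding genes had −0.02, −0.03 and −0.03, rRNA processing genes −0.03, −0.07 and −0.05, and cell division genes −0.03, −0.03 and −0.02, each below every random list. Genes of the cytosolic small ribosomal subunit were lower in PPD and PPT than in the library labelled E2, with medians of −0.09 and −0.07, but this library itself lay above control (0.04, percentile 99), and against control PPD had −0.03 (percentile 6.67) and PPT −0.04 (percentile 1.67), neither reaching 2.5 standard deviations.

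ITGB6, IGFBP3 and CDKN2B, which lie outside the lists and were chosen after their values were seen, were higher than in control. ITGB6, an integrin subunit gene, was 2.27-fold (1.78 to 2.92), 2.52-fold (1.98 to 3.22) and 2.13-fold (1.65 to 2.76) higher in E2, PPD and PPT. IGFBP3, a binding protein of insulin-like growth factors, was 1.74-fold (1.36 to 2.23), 2.15-fold (1.70 to 2.75) and 2.15-fold (1.69 to 2.76) higher, and CDKN2B 1.59-fold (1.30 to 1.95), 1.96-fold (1.62 to 2.39) and 1.5-fold (1.2 to 1.9). IGFBP4, an estrogen-induced gene, was 1.52-fold (1.48 to 1.58), 1.75-fold (1.69 to 1.81) and 1.74-fold (1.68 to 1.81) lower.

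The estrogen-induced genes were lower, and the estrogen-repressed genes higher, in the library labelled E2 than in that labelled control. Library size or scaling was not the cause, since a factor common to all genes of a library moves matched random lists as much, and the central 95% of these ran from −0.04 to 0.05 against an induced median of −0.38 (bootstrap interval −0.66 to −0.25). A lower share of luminal cells was not seen, as 11 luminal markers outside the estrogen-induced list had a median of 0.02 (bootstrap interval −0.06 to 0.10), far from −0.38. An exchange of the control and E2 labels may account for it, but the test used does not decide this. The 33 measured proliferation genes outside the estrogen lists, which estrogen raises in these cells, had a median of −0.06 (percentile 0.04 among random lists), with 24 lower in the library labelled E2. The test took the direction only and set no size that an exchange predicts. A real fall in estrogen signalling in the library labelled E2 predicts the same direction. Dose, medium and a single wrong label also stay open, untested.

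Genes that differed 2-fold were mostly short with few counts. Counting noise may be the source of most of them between PPT and PPD, since simulations without differing genes gave a median of 44. The noise as simulated did not give all of them, as the observed 78 lay above the highest simulation, 64. The simulations took reads as independent, so wider counting noise is not excluded as the source of the rest. Nor did the simulated noise account for the 18 genes with a mean count of at least 50 that differed 2-fold between PPD and the library labelled control, where 100 simulations gave 0. Against the library labelled E2 only 1 gene differed, within the simulations, so the count of 18 rests on the control label. Variation between cultures or library preparations was not measured here and stays open for all of these genes.

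PPD and PPT differed from control in the same direction as the library labelled E2. For PPD the counting noise of the shared control, as simulated, was too small for this. The covariance of 0.0325 between E2 and PPD lay above the highest of 100 simulations, 0.0152. For PPT only the simulated median was compared, 0.0125 against an observed 0.0328. A difference of the single control library from the other 3 cannot be told apart from an effect that the compounds share, as there was no second control. Both leave the covariance above the simulated median, for PPD by 0.0199. If the labels of control and E2 were exchanged, PPD and PPT would stand slightly below the untreated library in these genes, a hypothesis that these libraries alone do not test.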
